A study of Homo sapiens with 6 samples.

How the data were processed

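Total RNA from LNCaP cells was sequenced on an Illumina HiSeq instrument after TruSeq total RNA library preparation, per the labels' protocols. The cells had been infected with control or FOXA1 hairpin lentivirus and selected with puromycin. The submitters' processing notes name STAR and the build hg38, with no version and no role. The read counter, the gene annotation and the way the values were normalised are not given in the sources used here.

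The authors deposited 1 table for the series, with 26475 rows of gene names and 6 value columns. Its name calls the values RPKM. The deposited table heads the value columns with codes that no label of the samples or the series contains, so none of the 6 value columns was used for any result. They were looked at only to learn what the table holds, which included values of FOXA1, TGFB3, KLK3 and GAPDH, and some rows hold no values, so a gene name in the table does not mean that the gene has a value. The groups of the samples come from their titles. The only column used was that of the gene names, a text column with no unit, as deposited by the authors.

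Gene names were compared, as exact strings, with the gene names of GENCODE release 29 (GRCh38) and, as an alternative, also with RefSeq symbols and synonyms of GRCh38.p14. Symbols of the gene lists that were absent as written were also looked up under their RefSeq names, a step added after the data were examined. Coordinates are 1-based positions of GENCODE release 29, whose assembly GRCh38 is the one that hg38 names. A set of 26 gene lists and 12 named genes had been fixed before the data were examined, together with a limma test on log2 values, gene list tests and a set of alternatives. One of the named genes is not reported here. None of these tests was run, because each needs the group of every column. No simulated data were made, because no statistic across genes was computed. The work used Python 3.11.15 and pandas 2.3.3.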

Results

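RNA was sequenced from LNCaP cells, an established androgen-responsive line of human prostate cancer, to ask how knockdown of FOXA1 changes gene expression. FOXA1 is a forkhead pioneer factor that opens chromatin for other transcription factors. The labels describe 6 samples in 2 groups. In 3 samples the cells carried the control lentiviral vector pGIPZ, and in 3 they carried a short hairpin RNA against FOXA1. The titles number the samples 1 to 3 in each group, and nothing in the labels says whether these were separate cultures.

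The design implies a single comparison, FOXA1 knockdown against control vector, and its values are not reported here. The table of expression values has 6 value columns, and 0 of their codes occur in any title, description or other label of the samples. No column was therefore assigned to a sample or to a group. Column order was not used, since nothing links it to the samples, and FOXA1 level was not used, since it is an outcome of the comparison. No expression level, fold change, error or test of any gene is given, and library depth was not assessed.

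The genes that the comparison concerns each had 1 row in the table. FOXA1 (ENSG00000129514.5) lies on the minus strand of chromosome 14, from 37589984 to 37596059, in GENCODE release 29 on GRCh38. TGFB3 (ENSG00000119699.7), which encodes a ligand of the TGF-β pathway named in the title of the study, lies on the minus strand of the same chromosome from 75958099 to 75982991. KLK3 (ENSG00000142515.14), which encodes prostate-specific antigen, lies on the plus strand of chromosome 19 from 50854915 to 50860764. SNAI2 (ENSG00000019549.11), which encodes a transcription factor of the epithelial to mesenchymal transition, lies on the minus strand of chromosome 8 from 48917604 to 48921740. Each of these genes is annotated as protein-coding.

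The table covered most of the gene groups chosen for the comparison. All 28 TGF-β ligands, receptors and signal carriers had a row, as did all 31 mesenchymal genes, all 21 epithelial junction genes and all 23 neuroendocrine genes. Of 30 symbols listed as androgen-responsive genes, 28 were present, and the absent symbols were ACP3 and PLPP1. ACP3 is another name of ACPP, which was also listed and is among the 28 present. The RefSeq synonym PPAP2A of PLPP1 was not listed but was in the table. Of 34 symbols listed as TGF-β response genes, 32 were present, and the absent symbols were CCN1 and CCN2. These are other names of CYR61 and CTGF, which were also listed and are among the 32 present. No gene of this list was therefore without a row. The 15 symbols of mitochondrially encoded genes were not found, either as written or under the RefSeq names tried. These counts are of gene names that head a row and say nothing of expression.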

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

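No comparison between the groups was computed, so none of the settings chosen for it (pseudocount, filter on low values, scaling, trend, sample weights, leaving out each sample, and the forms of the gene list test) was tried. No paired analysis was possible because the value columns carry no replicate number and could not be matched to the samples. Nor do the labels say that equal numbers in the titles mark a shared day or culture. The match of gene names was run in 2 ways, both chosen after seeing the data. Of 26473 different names, 23873 (90.2%) matched GENCODE release 29, and 25392 (95.9%) matched when RefSeq symbols and synonyms were also allowed. The wider match accepted a synonym of any gene, and a synonym can be shared between genes, so it does not identify the gene.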

Other observations

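In the column of gene names, 28 rows hold a calendar date in place of a symbol, a form that spreadsheets give to some gene symbols. Of these rows, 13 have a date in Mar, 14 a date in Sep and 1 a date in Dec. The names 1-Mar and 2-Mar each stand on 2 rows. GENCODE release 29 has 11 genes named MARCH and 2 named MARC with a number, against the 13 rows with Mar, and 13 genes named SEPT with a number, against the 14 rows with Sep. Rows with a repeated date name cannot be assigned to a gene from the name alone.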
